A study of Gallus gallus with 4 samples.

How the data were processed

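Small RNA of 19 to 38 nucleotides was gel-purified from midbrain tissue of chick embryos incubated for 30 h at 37 °C, per the labels' protocols, and cloned with a standard Illumina small RNA protocol with or without prior periodate oxidation. The authors deposited raw counts of reads per feature, 1 value per row and library, and per the submitters' processing notes they were made with featureCounts on the chicken build galGal6. The aligner, the treatment of reads that map to several places, the annotation and the version of the counter were not given in the sources used here. That choice matters most for TE families, tRNAs and rRNA, whose copies share reads, so the split of reads between near-identical families is uncertain. Each library had 6 tables: TE families (241 rows), miRNA (1140), other genes (23216), other repeats (34), tRNA (54) and rRNA (4), 24689 rows in all, of which 12127 were at 0 in every library. Each table came as unstranded and as reverse-strand counts, which makes 48 count files, all of them read.

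The reverse tables were read as antisense because tRNA, whose strand is known, had at most 0.0026% of its reads there, and miRNA 0.0751% and 0.0767% in the total libraries. In the oxidized libraries the miRNA share there was higher, at 1.04% and 1.65%, and 97.9% of these reads came from 1 ID. Reverse counts are not strictly a part of the unstranded counts: 190 rows, 4 of them TE families, had more reverse than unstranded reads in some library. Antisense shares of single small families are therefore approximate. Other genes were counted without regard to strand unless stated, so a gene and an antisense partner cannot be told apart. In 3 cases an ID of the miRNA table and one of the table of other genes, each with at least 500 reads in all, had identical counts in the 4 libraries, and 2 of these miRNA IDs were called higher after oxidation.

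The miRNA and other-gene tables use Ensembl IDs. A RefSeq table of gene names from another assembly (GRCg7b) was searched for them, and 0 of 24356 IDs matched. The 19 of 30 lists that needed gene or miRNA names therefore had no members, and no gene is named. These lists were the early embryo, neural, neural crest, muscle and heart, blood and endothelium, Hox cluster and liver miRNAs, and the piRNA pathway, neural crest, neural plate, mesoderm, blood, endoderm, ectoderm, ribosomal protein, snoRNA, snRNA, histone and mitochondrial genes. The list of LINEs outside CR1 had 1 tested member and was not tested, since 3 were required. No coordinates were used.

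Depth was the summed unstranded count over the 6 tables, from 10981001 to 17962725 reads per library. A CPM value is a count divided by that sum. A count of 0 allows up to 3 reads, which is 0.120 CPM over both oxidized libraries. Binomial intervals (exact, 95%) and floors cover counting error alone, since PCR copies are not independent molecules. Reads per molecule were estimated for the oxidized libraries after the data were seen: in other-gene rows with at least 20 reads in one oxidized library and 0 in the other, the median was 122 reads (202 rows) in oxidized replicate 1 and 130.5 reads (218 rows) in oxidized replicate 2. Taken as the reads of 1 molecule, these give about 90010 and 107900 assigned molecules. Replicates were not copies of each other, with a chi-square per degree of freedom of 256.5 between the oxidized libraries and 197.6 between the total libraries.

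Before the data were examined, the groups, the test, the lists, the alternatives and the rule for named features were fixed. Counts of all tables were fitted together with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with the default expression filter, which kept 1326 features, and Benjamini-Hochberg adjustment over all of them at 0.05. No TMM factor was used, because TMM assumes that most features are unchanged, which was not expected between oxidized and total libraries, so a fold change is a change in the share of assigned reads. TMM factors would shift the median log2 fold change by -0.17, and DESeq2 size factors by -0.15. Leaving miRNA out of the library size, an alternative chosen after the data were seen, shifts it by -1.74. Folds in the text are ratios of mean CPM. Lists were tested with camera in limma 3.58.1. Shares were compared by exact two-sided permutation tests with scipy 1.17.1. Features were named where they had the highest or lowest fold changes of a table among those past the threshold with a mean of at least 20 counts and no overlap between groups (5 each for TE families, 6 and 4 for other genes, 3 and 5 for miRNA, 2 each elsewhere). The 3 most abundant in each group of the TE, miRNA and other-gene tables, up to 4 abundant members of each list and the ENS elements were added. PIWIL1 was to be named in any case but could not be looked up without gene names.

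Same-numbered oxidized and total libraries were taken as portions of 1 sample, since the series describes each sample as divided, although the labels do not say outright that the numbers mark the portions. As a check, the deviations of same-numbered libraries correlated at 0.053 over all tested features, 0.077 over TE families, 0.032 over miRNA, 0.066 over other genes, 0.50 over the 22 other repeats and -0.32 over tRNA. The oxidized libraries spread more: the SD of the log2 ratio between replicates was 2.53 for oxidized and 0.58 for total libraries. The fit assumes 1 spread for both groups, so calls without a total library rest mostly on the oxidized ones.

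The scripts were tested on simulated counts with the real library sizes, dispersions and 1326 features. With 100 features changed 8-fold and 100 changed 50-fold, edgeR recovered 6% and 28% of them, with median fitted sizes of 3.00 and 5.68 log2, and called 1 of 1126 unchanged features. DESeq2 1.42.0 recovered 43% and 93% and called 29 unchanged ones. A second simulation was added because the first recovered few changes. In it every feature was changed as the real fit had estimated, and edgeR called 958 of 1326, 3 of them with the wrong sign, and 91.8% of those changed over 8-fold. Its changes and dispersions came from the real fit, so it shows only that the fit returns its own calls. Both simulations gave the 2 groups 1 spread, unlike the real libraries, so neither gives the error rate of the real calls. Alternatives were TMM, DESeq2, 3 other library sizes, no filter or a filter of at least 50 reads in 2 libraries, a fit per table, a minimum fold of 1.5, sense counts, the replicate block, each library left out, a voom fit with a variance per group, and oxidized reads counted as molecules. The voom fit, the molecule counts, and the library size and denominators without miRNA were chosen after the data were seen, and the others before. Versions of the remaining tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.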

Results

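Small RNA from the midbrain part of the head of wild-type chick (Gallus gallus) embryos at Hamburger-Hamilton stage 9 minus was sequenced in 4 libraries. At this stage the neural folds of the midbrain are closing and neural crest cells are about to leave them. Each sample was divided into an oxidized portion and an untreated portion, called total here. Sodium periodate destroys the 3′ end of RNAs whose last ribose is unprotected, so an oxidized library keeps RNAs with a 2′-O-methyl group there, the mark of PIWI-interacting RNAs (piRNAs). The design gives 2 oxidized and 2 total libraries, and the comparison asks which small RNAs of the cranial region withstand oxidation. The reads assigned to a feature numbered 10981001 and 14081954 in oxidized replicates 1 and 2, and 17962725 and 14946049 in total replicates 1 and 2. Nothing in the labels says that the replicates came from separate pools of embryos, so p-values measure the spread between these samples, which may be technical.

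Transposable element (TE) reads and tRNA reads made up most of the oxidized libraries, whereas miRNA reads made up most of the total libraries. TE reads were 47.3% ± 1.68 of assigned reads after oxidation and 0.940% ± 0.102 in total libraries (mean ± SD, n = 2 each), a 50.4-fold higher share. The miRNA share moved the other way, from 71.9% ± 5.27 in total libraries to 1.59% ± 0.0416 after oxidation, 45.1-fold lower. TE reads numbered 31.0 and 28.4 per miRNA read in the oxidized libraries, against 0.0115 and 0.0149 in the total libraries. The tRNA share was 36.1% ± 0.0565 against 16.4% ± 3.25, that of other genes 7.57% ± 0.842 against 4.56% ± 0.803, and that of rRNA 7.10% ± 0.825 against 5.83% ± 1.07.

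In each single library these shares were narrow in counting error: the exact 95% binomial interval of the TE share was 48.5 to 48.6% in oxidized replicate 1 and 0.863 to 0.872% in total replicate 1. With 2 libraries against 2 there are 6 arrangements, so the smallest two-sided p of an exact permutation test is 0.333. That p was obtained for the TE share, the miRNA share, their ratio and the TE antisense share (0.333 after Benjamini-Hochberg adjustment over these 4 comparisons). A share depends on what else is in the library. Among reads other than miRNA, TE reads were still 14.3-fold higher after oxidation (48.1% ± 1.69 against 3.37% ± 0.267), but tRNA took a lower share than in total libraries (36.7% ± 0.042 against 58.3% ± 0.629), as did other genes (7.69% ± 0.859 against 16.3% ± 0.189) and rRNA (7.21% ± 0.842 against 20.8% ± 0.0852).

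**Figure D1:**
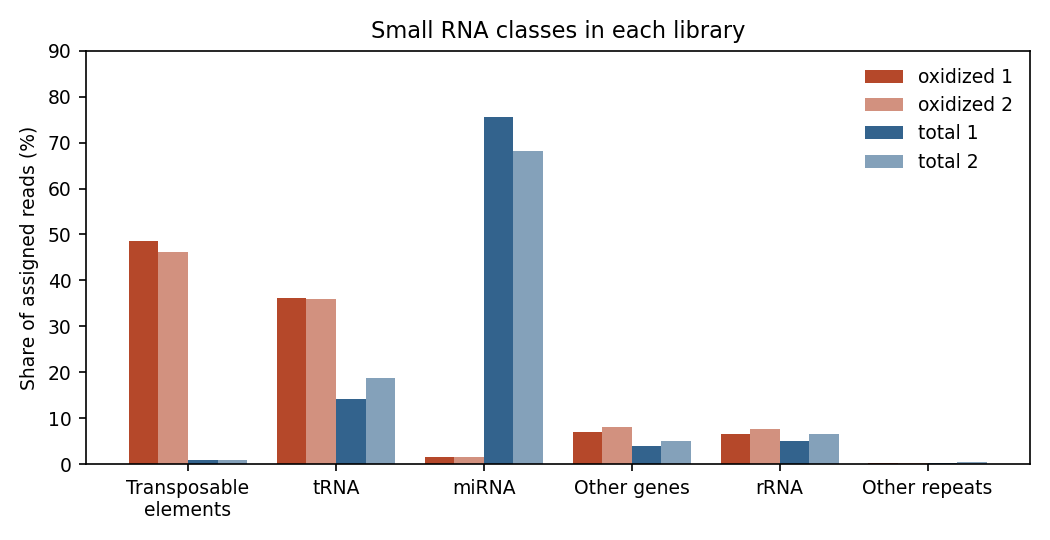
Share of assigned reads (%, vertical axis) in each of 6 feature classes (horizontal axis), with 1 bar per library, red for oxidized and blue for total, the paler bar being replicate 2. TE reads took 48.5% and 46.1% of the oxidized libraries, and miRNA reads 75.6% and 68.2% of the total libraries.

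Most TE families rose after oxidation. Of 105 families tested, 71 rose, 19 fell and 15 did not pass (edgeR quasi-likelihood test, adjusted p under 0.05). Of the 19 lower families 15 were expected under 3 molecules in the oxidized libraries at an unchanged share, by an estimate of 122 and 130.5 reads per molecule that was made after the data were seen and is itself untested. Counted as molecules, that is with oxidized reads divided by this estimate and rounded, 73 families were higher and 5 lower. A feature with few reads thus becomes one with 0 molecules. The CR1 family, chicken repeat 1, is the main LINE retrotransposon of bird genomes. Of its 29 tested subfamilies 23 rose, by 3.88- to 117-fold, and CR1 reads went from 0.589% ± 0.081 to 32.6% ± 1.12 of the library (n = 2). CR1-F alone rose 104-fold, from 1287 ± 229 to 134068 ± 13705 counts per 1000000 assigned reads (CPM; log2 fold change 6.70, SE 0.22, edgeR adjusted p = 0.0014). CR1-C3 had the highest fold change of all TE families, 117-fold (log2 fold change 6.87, SE 0.33), while CR1-B, CR1-G and CR1-C rose 60.5-, 57.6- and 49.7-fold and CR1-B2 only 10.1-fold.

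Long terminal repeat (LTR) retrotransposons, which include the endogenous retroviruses, mostly rose as well. Of 57 tested families 46 rose, by 7.54- to 113-fold, and their share went from 0.226% ± 0.0398 to 14.7% ± 0.579 of the library. GGLTR7B rose 113-fold, the internal part of GGERVL-C 108-fold and that of GGERVL-B 86.4-fold, the last from 592 ± 99.6 to 51204 ± 7150 CPM. GGERV22_LTR rose 81.2-fold, GGERVL18-int 68.1-fold and GGERV20_I-int 52.7-fold. ENS-1, also called Soprano, is a chick LTR element transcribed in the early embryo and related to the ERNI gene of the prospective neural plate. Its LTRs rose, ENS1B-LTR 56.8-fold (2113 ± 299 against 37.2 ± 6.84 CPM) and ENS1-LTR 44.5-fold. ENS3-int rose 43.6-fold, but the internal part ENS1-int only 10.1-fold (280 ± 67.96 against 27.7 ± 1.18 CPM), and its call was lost without total replicate 1 (adjusted p = 0.081) or total replicate 2 (adjusted p = 0.083).

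A smaller set of TE families had few or no reads in the oxidized libraries. DNA transposons, as grouped by name, had 7 of 10 tested families lower and 1 higher. This grouping did not match Harbinger-N276_AMi, Harbinger-N1_Croc or Char12Mar1_GG, whose names are also those of DNA transposons. The counts are therefore those of the list, not of the whole class. Chompy-2_Croc held 18895 and 12548 reads in the total libraries and 13 in each oxidized library, 898-fold lower in mean CPM (edgeR adjusted p = 0.0015). Eulor9A had 441 and 362 reads in the total libraries and none after oxidation, Eulor9C went from 2013 and 1267 reads to 0 and 1, and Chompy-6_Croc from 573 and 488 to 1 and 0. If that estimate holds, at an unchanged share 187 molecules would be expected over both oxidized libraries for Chompy-2_Croc, 19.5 for Eulor9C, 6.39 for Chompy-6_Croc and 4.83 for Eulor9A. The size of their fall would then be poorly bounded, and no bound is given. Harbinger-N276_AMi, which the list did not match, had 171 and 113 reads against none, but by the estimate only 1.69 molecules would be expected. Its call was lost when reads were counted as molecules (adjusted p = 0.19) and with the replicate block (adjusted p = 0.23). Mariner1_GG was the family of the list that rose, 9.50-fold (84.8 ± 22.9 against 8.92 ± 1.67 CPM), a call lost with miRNA left out of the library size (log2 fold change 1.44, down from 3.25, adjusted p = 0.065). Without total replicate 1 the calls of Mariner1_GG (adjusted p = 0.29), Eulor9A (0.30), Eulor9C (0.070), Chompy-6_Croc (0.26) and Harbinger-N276_AMi (0.30) were lost. Without total replicate 2 the same calls were lost except that of Eulor9C (edgeR adjusted p = 0.24 for Mariner1_GG and 0.31 for Eulor9A).

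Of the 3 SINE families tested, MIR_Aves1 and LFSINE_Vert fell to 0 reads from 20 and 16 and from 27 and 19, where by the estimate 0.216 and 0.275 molecules would be expected at an unchanged share, so a count of 0 would say little. Both calls were lost counted as molecules (adjusted p = 0.62), with the replicate block (0.30) and without either total replicate (0.30 and 0.31). AmnSINE1 did not pass, with 118 reads in oxidized replicate 1 and 0 in oxidized replicate 2. Neither did L2-1_CPB, the LINE outside CR1, with 0 and 177, nor MER133A, with 118 and 3, although MER133A was called lower when counted as molecules (log2 fold change -3.46, adjusted p = 0.0079). The few fallers inside the rising groups, named after their values were seen, were CR1-8_Crp among CR1 and GGLTR3G1, GGLTR3G2, GGLTR8A, GGLTR8B and GGLTR9 among LTR elements. Among families that no superfamily list matched by name, Char12Mar1_GG rose 3.68-fold, and Harbinger-N1_Croc, REP131 and UCON29 fell together with Harbinger-N276_AMi. With the replicate number as a block, 55 families were higher and 4 lower. Without total replicate 1 the counts were 41 and 1, and without total replicate 2 they were 41 and 2, because the lone total library is then assumed to vary as the oxidized ones do.

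**Figure D2:**
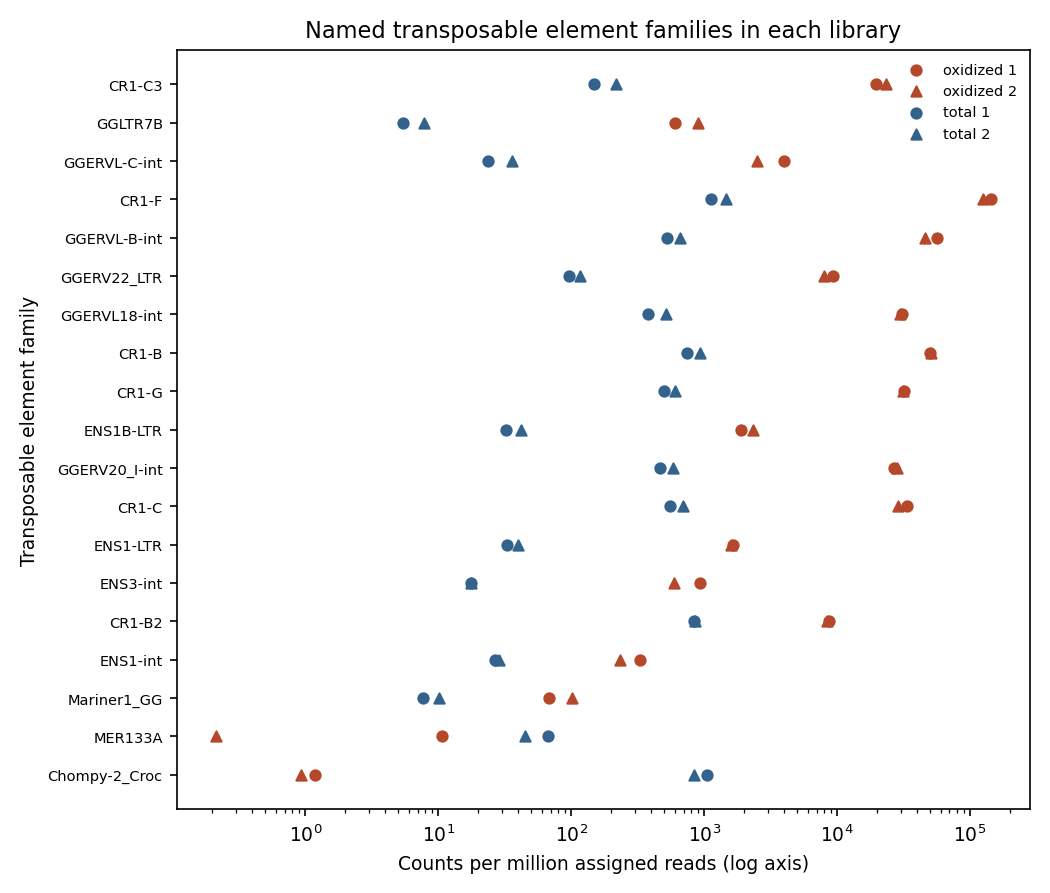
CPM (horizontal log axis) of the named TE families with at least 1 read in every library (vertical axis), with red points for oxidized and blue for total libraries, circles for replicate 1 and triangles for replicate 2. CR1-F lies near 134068 CPM after oxidation and near 1287 CPM in total libraries, and Chompy-2_Croc is the clearest family on the other side, near 1.05 and 946 CPM.

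TE small RNAs were mostly antisense to the annotated element, and more so after oxidation. Reverse-strand reads were 95.9% ± 0.547 of TE reads in the oxidized and 77.9% ± 3.04 in the total libraries (n = 2), a difference of 18.02 percentage points. DNA transposons, as grouped by name, made up 12.8% ± 3.35 of TE reads in total libraries, where 11.6% of their reads were antisense. After oxidation they made up 0.0284% of TE reads. Part of the difference thus came with the loss of these mostly sense reads. CR1 reads were 97.7% ± 0.117 antisense after oxidation and 88.1% ± 0.919 before, and LTR reads 92.1% ± 1.49 and 86.9% ± 0.407. CR1-C3 reached 99.7% after oxidation and CR1-B 99.2%. ENS1B-LTR was 88.5% antisense after oxidation and ENS3-int 97.3%, whereas ENS1-int was 24.4% antisense after oxidation and 11.3% in total libraries. Chompy-2_Croc had no antisense read in any library, and Eulor9C was 99.97% antisense in total libraries.

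Counting the reverse strand alone, 65 of 85 tested families were higher after oxidation and 12 lower (edgeR quasi-likelihood test). Scaling to that strand ended many of these calls, and the cause was not tested. TMM factors gave 26 higher and 19 lower, and DESeq2 gave 27 and 27. With the replicate block 54 were higher and 2 lower, and without total replicate 1 or 2 the counts were 51 and 2 or 53 and 10.

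The miRNA IDs that passed mostly fell after oxidation. Of 385 tested IDs 315 fell, 4 rose and 66 did not pass. Of the 315, however, 178 were expected under 3 molecules at an unchanged share by the untested estimate above, and counted as molecules 153 IDs were lower and 4 higher. The miRNA table lists Ensembl IDs, which the files do not pair with names, so miRNAs are not named here. The most abundant ID, ENSGALG00000021771, went from 254606 ± 4149 to 2057 ± 68.3 CPM, 123.8-fold lower (log2 fold change -6.95, SE 0.11, edgeR adjusted p = 0.00081, lower in both oxidized libraries). The other IDs among the 3 most abundant in total libraries fell 132.6-fold and 111.8-fold. Other abundant IDs fell less. Among the 3 most abundant after oxidation, ENSGALG00000018326 fell 29.4-fold (1489 ± 19.5 against 43712 ± 162 CPM). ENSGALG00000026107 fell 6.85-fold (1502 ± 229 against 10282 ± 2124 CPM). The 5 lowest fold changes belonged to IDs with no read after oxidation and 45.3 to 109 CPM in total libraries, where 8.96 to 21.5 molecules would be expected by that estimate. Among the risers, ENSGALG00000034406 rose 28.2-fold, from 8 and 4 reads to 74 and 188, a call lost with the replicate block (edgeR adjusted p = 0.30). ENSGALG00000033220 rose 6.63-fold. Its call was lost with miRNA left out of the library size (log2 fold change 0.91, edgeR adjusted p = 0.15), which left 2 IDs higher. ENSGALG00000036151 rose 10.1-fold (392 ± 69.2 against 39.0 ± 2.52 CPM), and its 4 counts were identical to those of an ID in the table of other genes, so the same reads appear to stand in both tables. Its call was lost without total replicate 1 (edgeR adjusted p = 0.058) or 2 (adjusted p = 0.057), as were those of the 5 IDs with no read after oxidation. With the replicate block 135 IDs were lower and 2 higher. Without total replicate 1 the counts were 57 and 0, and without total replicate 2 they were 63 and 0 (edgeR, with 2 and 3 higher at an unadjusted p under 0.05).

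Transfer RNA fragments moved apart by type. Of 50 tested tRNA rows 16 rose, 11 fell and 23 did not pass, and counted as molecules 21 rose and 5 fell. The highest fold changes were 62.2-fold for tRNA-Ala-GCY_ (2054 ± 142 against 33.0 ± 13.3 CPM; log2 fold change 5.96, SE 0.44, edgeR adjusted p = 0.0038), 27.6-fold for tRNA-Ala-GCY, 26.8-fold for tRNA-Ala-GCG and 26.6-fold for tRNA-Ser-TCY. The most abundant riser, tRNA-Gly-GGY, rose 1.83-fold, from 60646 to 110737 CPM (adjusted p = 0.024). Its call was lost with TMM, DESeq2 and voom (adjusted p = 0.073, 0.088 and 0.090), without oxidized replicate 1 (0.051), oxidized replicate 2 (0.12) or total replicate 1 (0.12), and turned to lower with miRNA left out of the library size (log2 fold change -0.93, adjusted p = 0.0045). tRNA-Val-GTY rose from 9716 to 82668 CPM, and tRNA-Val-GTG from 7227 to 35539 CPM. The most abundant row of the total libraries, tRNA-Glu-GAG_, stood at 71362 CPM there and 90105 CPM after oxidation and did not pass (adjusted p = 0.13). Leucine row tRNA-Leu-TTG fell from 370 to 68.8 CPM and tRNA-Arg-CGY from 493 to 103 CPM, while tRNA-Leu-TTA went from 83 and 76 reads to 0 and 1, and tRNA-Thr-ACG from 96 and 39 to 1 and 0. The rows other than tRNA-Ala-GCY_, tRNA-Ala-GCY, tRNA-Leu-TTA and tRNA-Thr-ACG were picked after their values were seen. The calls of tRNA-Leu-TTG and tRNA-Arg-CGY were lost without total replicate 1 (adjusted p = 0.12 and 0.13) or total replicate 2 (0.10 and 0.11). For tRNA-Leu-TTA and tRNA-Thr-ACG only 0.960 and 0.787 molecules would be expected by the estimate. Their calls were lost counted as molecules (adjusted p = 0.36 and 0.42), with the replicate block (0.30 for both) and without either total replicate (0.30 and 0.31 for both).

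The balance of tRNA calls depended on the scaling: it was 22 higher and 8 lower with rRNA and tRNA left out of the library size, and 8 higher and 24 lower with miRNA left out. With the replicate block it was 13 and 2. Without total replicate 1 it was 9 and 0, and without total replicate 2 it was 10 and 0 (edgeR, with 3 and 2 lower at an unadjusted p under 0.05), and without oxidized replicate 1 or 2 it was 21 and 17 or 23 and 20.

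**Figure D3:**
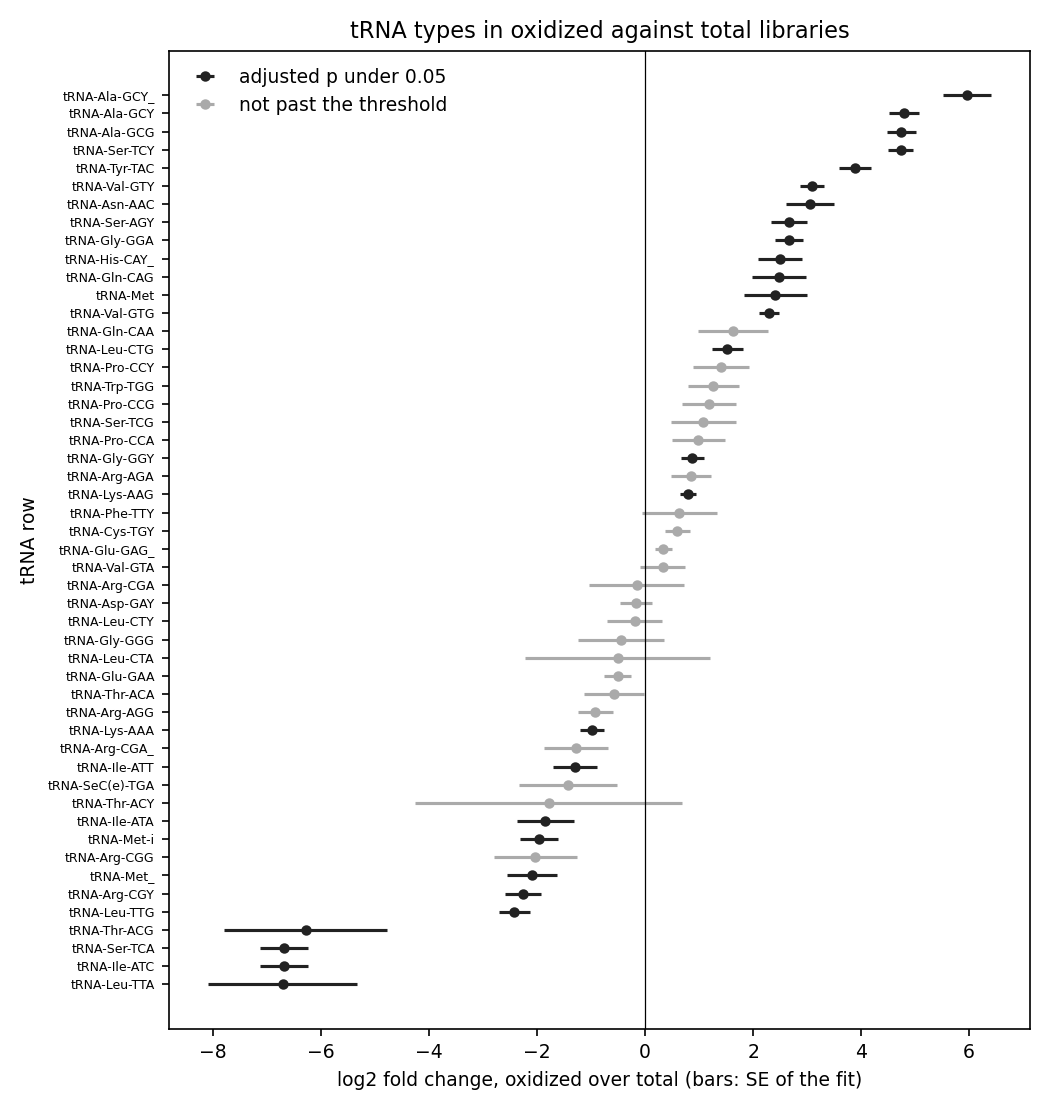
Log2 fold change of oxidized over total libraries (horizontal axis) for the 50 tested tRNA rows (vertical axis), with bars for the SE of the fit and black points for rows past the threshold. Points run from -6.71 for tRNA-Leu-TTA to 5.96 for tRNA-Ala-GCY_.

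Among repeats outside the TE table, 3 of 22 rose and 9 fell. Z-REP, the macrosatellite of the Z chromosome, rose 75.1-fold (2273 ± 286 against 30.3 ± 13.4 CPM; edgeR adjusted p = 0.0041), and the satellite Sat-CR1_GG rose 27.5-fold. The spliceosomal RNA U5 fell 10.5-fold (279 ± 15.2 against 2927 ± 369 CPM; edgeR adjusted p = 0.0025), and G-rich repeats fell 5.38-fold. A-rich repeats rose 2.92-fold and U1 and U6 fell, all 3 named after their values were seen. Of the 4 rRNA rows the small subunit rose 3.10-fold and 5S fell 2.06-fold. With miRNA left out of the library size the small subunit row was no longer higher (log2 fold change -0.20). The replicate block left 1 repeat higher and 1 lower, and no rRNA row lower, and ended the calls of Sat-CR1_GG (adjusted p = 0.051), G-rich repeats (0.053) and 5S (0.061). Leaving out total replicate 1 or 2 gave the same counts and ended the same 3 calls. Counted as molecules, 3 repeats were higher and 3 lower.

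Far fewer other genes were seen after oxidation. A read fell on 647 and 646 IDs in the oxidized libraries and on 9266 and 8901 in the total libraries. Of 760 tested IDs 113 rose, 405 fell and 242 did not pass. Of the 405, however, 377 were expected under 3 molecules at an unchanged share by the untested estimate, and counted as molecules 36 IDs were lower and 99 higher. The files do not pair these IDs with names either. Among the 3 most abundant after oxidation, ENSGALG00000038243 rose 65.2-fold (3517 ± 634 against 53.9 ± 15.1 CPM, edgeR adjusted p = 0.0025). ENSGALG00000032059 rose 38.9-fold (2428 ± 301 against 62.4 ± 10.7 CPM, edgeR adjusted p = 0.0019). Both calls held with the replicate block and voom. ENSGALG00000030470, abundant in total libraries, fell 9.45-fold (edgeR adjusted p = 0.019), a call lost without either total replicate. Of the 6 IDs named for the highest fold changes, ENSGALG00000052968 ranked last. It rose 133.4-fold (315 ± 19.9 against 2.36 ± 0.349 CPM, edgeR adjusted p = 0.0019). All of its reads lay on the reverse strand in both kinds of library. ENSGALG00000053369, ENSGALG00000043077 and ENSGALG00000048641 ranked above it (log2 fold change 8.72, 8.68 and 7.65). Their calls were lost with the replicate block (edgeR adjusted p = 0.30 for each) and without either total replicate. That of ENSGALG00000048641 was also lost with voom (adjusted p = 0.12). ENSGALG00000051188 (log2 fold change 7.55) lost its call without either total replicate, and ENSGALG00000030533 (log2 fold change 7.16) without total replicate 1. ENSGALG00000043598 fell 3.36-fold (2310 ± 401 against 7761 ± 2584 CPM; edgeR adjusted p = 0.011), a call lost without total replicate 2 (adjusted p = 0.062) and with voom (adjusted p = 0.090). The 4 IDs named for the lowest fold changes had no read after oxidation. They stood at 15.8 to 24.2 CPM in total libraries, where 3.13 to 4.8 molecules would be expected by the estimate. Their calls were lost without either total replicate. Those of ENSGALG00000025648 and ENSGALG00000027915 were also lost with the replicate block (edgeR adjusted p = 0.061 and 0.078) and counted as molecules (0.052 and 0.066). A single ID, ENSGALG00000039489, held 66.0% ± 3.67 of other-gene reads after oxidation and 54.2% ± 1.12 in total libraries. It rose 2.03-fold (50143 ± 8337 against 24760 ± 4863 CPM, edgeR adjusted p = 0.016). Its call was lost without oxidized replicate 2 or total replicate 1. With miRNA left out of the library size it was called lower (log2 fold change -0.79, edgeR adjusted p = 0.012). The oxidized replicates had 312 IDs in common, but 270 of the 502 IDs with at least 100 reads in either had no read in the other, against 0 of 163 in the total libraries. With the replicate block 27 were higher and 24 lower. Without total replicate 1 the counts were 10 and 2, without total replicate 2 they were 12 and 1, and without oxidized replicate 1 or 2 they were 203 and 510 or 188 and 520.

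**Figure D4:**
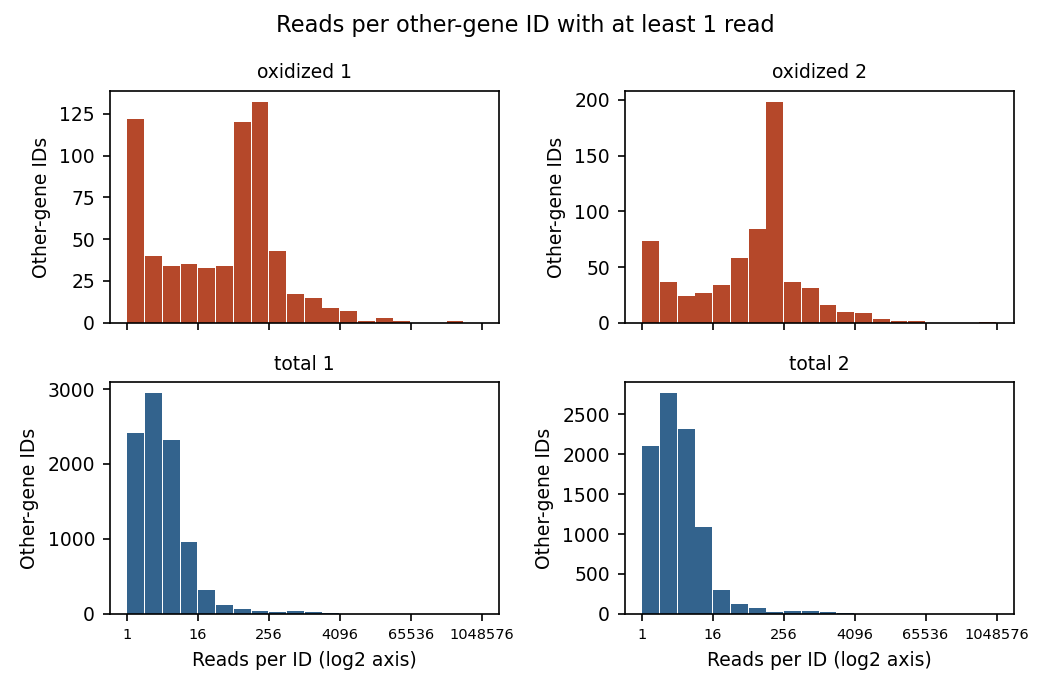
Number of other-gene IDs (vertical axis, its scale differing between panels) by reads per ID (horizontal log2 axis), 1 panel per library, for IDs with at least 1 read. In the oxidized libraries 249 and 263 IDs hold 51 to 200 reads and form a separate peak. A further 149 and 96 IDs there hold 1 to 2 reads, and 139 and 135 hold 3 to 50. In the total libraries 4892 and 4972 IDs hold 3 to 50 reads.

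Tested as lists against all other features, TE families, CR1 families, LTR families and tRNA rows moved up and miRNAs moved down (camera with a preset correlation of 0.01, 5 of 10 lists at adjusted p under 0.05). The adjusted p was 4.6e-26 for all TE families, 1.1e-16 for CR1, 4.6e-26 for LTR elements, 5.7e-06 for tRNA and 1.9e-13 for miRNA. None of the 5 held with an estimated correlation, where the adjusted p was 0.14 for TE, CR1 and LTR lists, 0.28 for miRNA and 0.20 for tRNA (3 of 10 lists at an unadjusted p under 0.05). Against the other features, most of which fell as well, DNA transposons and SINEs did not pass (adjusted p = 0.48 and 0.53), nor did other genes (0.43), other repeats (0.53) and rRNA (0.082). For other genes and other repeats the median and mean log2 fold changes were negative while the direction against all other features was upward. With fry, which asks whether a list moves one way, 9 of 10 lists passed. With the replicate block the rRNA list also passed (adjusted p = 0.0499). Adjusted over the list alone, 71 TE families rose and 19 fell, 4 miRNA IDs rose and 316 fell, 23 CR1 families rose and 1 fell, 47 LTR families rose and 5 fell, and 16 tRNA rows rose and 9 fell. In the same way 113 other-gene IDs rose and 405 fell, 3 other repeats rose and 9 fell, 1 DNA transposon family (Mariner1_GG) rose and 7 fell, MIR_Aves1 and LFSINE_Vert fell, and the small-subunit rRNA row rose.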

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

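The separate reverse-strand counts of other repeats and other genes were not compared above, where both strands were counted together, and their sums stood above the level in the total libraries. Reverse-strand reads of the other-repeat table were at 1688 and 2137 CPM in the oxidized libraries (mean 1912) and at 115 and 142 CPM in the total libraries, 14.9-fold higher, and 96.4% of the oxidized reads among them came from Z-REP. Reverse-strand reads of the other-gene table were at 2076 and 2083 CPM (mean 2080) after oxidation and at 963 and 988 CPM before, 2.13-fold higher, spread over 194 IDs in the oxidized libraries and 3912 in the total libraries. ENSGALG00000052968 held 15.1% of the oxidized reads among the latter. Per 1000000 reads other than miRNA the other-gene sum turned lower, at 2109 and 2117 against 3950 and 3102, while the other-repeat sum stayed higher, at 1715 and 2172 against 470 and 446. Reverse-strand reads of the miRNA table were lower, at 163 and 267 CPM against 568 and 523 CPM. The sums were not tested, and single features of the other-gene and other-repeat tables moved both ways. Of the other-gene IDs tested on reverse counts 38 were higher and 42 lower (edgeR quasi-likelihood test), 11 and 59 with TMM factors, 5 and 62 with DESeq2, 19 and 2 with the replicate block, 11 and 4 without total replicate 1 and 12 and 40 without total replicate 2. Of 11 other repeats 2 were higher and 5 lower, 1 and 8 with TMM or DESeq2, 2 and 0 with the block (1 lower at an unadjusted p under 0.05), 1 and 1 without total replicate 1, 2 and 4 without total replicate 2 and 3 and 8 without oxidized replicate 1. No explanation is offered. No group had the 4 samples that an outlier test needs.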

How the results depend on the processing

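The direction of the TE and miRNA shares, their ratio and the antisense share was the same under all alternatives tried for them. The alternatives with reads counted as molecules, a variance per group, and miRNA left out of a library size or denominator were chosen after the data were seen. The TE share ratio of 5.65 log2 (SD 0.17) was 3.84 with miRNA left out of the denominator, 6.10 with rRNA and tRNA left out and 3.22 on sense counts, and the miRNA ratio of -5.50 was -5.04 with rRNA and tRNA left out. The TE to miRNA ratio of 11.14 log2 was 11.44 on reverse TE counts. With miRNA left out, tRNA, other-gene and rRNA share ratios turned to -0.67, -1.08 and -1.52 log2, and without rRNA and tRNA that of other repeats turned from -0.22 to 0.22. In these cases the denominator itself moves the ratio.

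Counts of calls moved more. Leaving out 1 library gave 41 to 78 TE families higher and 1 to 26 lower, 0 to 10 miRNA IDs higher and 57 to 361 lower, 10 to 203 other-gene IDs higher and 1 to 520 lower, 9 to 23 tRNA rows higher and 0 to 20 lower, 1 to 5 other repeats higher and 1 to 14 lower, 1 to 2 rRNA rows higher and 0 to 1 lower, and in reverse counts 51 to 69 TE families higher and 2 to 16 lower. The low ends came without a total library and the high ends without an oxidized one, where the fit rests on the tighter group. In 8 settings together (each library left out, block, TMM, DESeq2, voom) 41 TE families stayed higher and 1 lower, 56 miRNA IDs lower, 10 other-gene IDs higher and 1 lower, 1 other repeat higher and 1 lower, 9 tRNA rows higher and 1 rRNA row higher.

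With the replicate block there were 4 TE families lower, 2 miRNA IDs higher and 135 lower, 27 other-gene IDs higher and 24 lower, 2 tRNA rows lower, 1 other repeat higher and 1 lower, 0 rRNA rows lower and, in reverse counts, 2 TE families lower. It leaves 1 residual degree of freedom, and among the named features it ended 14 calls. It also gave -0.996 log2 for AmnSINE1 and -2.54 for L2-1_CPB, which were not called before, and 6 lists past the threshold. Counted as molecules, 5 TE families, 153 miRNA IDs, 36 other-gene IDs, 5 tRNA rows and 3 other repeats were lower. With miRNA left out of the library size, 2 miRNA IDs, 73 other-gene IDs, 8 tRNA rows and 0 rRNA rows were higher, and 24 tRNA rows and 2 rRNA rows lower. The most abundant other-gene ID then turned to -0.79 log2 and was called lower. SSU-rRNA_Hsa turned to -0.20 and L2-1_CPB to -1.30, and neither was called. Fewer features tested under the stricter filter left 10 TE families, 199 miRNA IDs, 79 other-gene IDs, 7 tRNA rows and 4 other repeats lower and 2 rRNA rows higher. With no filter 30 TE families and 2292 other-gene IDs were lower and 341 other-gene IDs higher, since 11639 were tested. Sense counts gave 11 TE families and 5 other repeats lower.

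The rRNA rows were 2 higher with DESeq2 and with a fit per table, and 0 lower without rRNA and tRNA in the library size, with a minimum fold of 1.5 and with voom. Reverse-count TE calls were 26 higher and 19 lower with TMM and 27 and 27 with DESeq2. Lists past the threshold were 0 with an estimated correlation and 9 with fry, which asks another question, and gave an adjusted p of 0.0029 with a downward direction for other genes and other repeats. AmnSINE1 went from 2.10 to -7.28 log2 without oxidized replicate 1, which alone held its oxidized reads, and to 3.12 without oxidized replicate 2, and L2-1_CPB to 1.51 without oxidized replicate 1, -9.01 without oxidized replicate 2 and -3.19 with voom. MER133A, not called in the main fit (-3.35), was called lower without oxidized replicate 1 (-7.99), without oxidized replicate 2 (-2.38) and counted as molecules (-3.46). Unless given, the cause was not tested.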

Other observations

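All values and tests in this part were chosen after the data were seen, and their bounds were written after the result, or an earlier test of the same pattern, was known. Some LTR families had mostly sense reads. Of 55 TE families with at least 500 reads in each oxidized library, 10 had a majority of sense reads in both: 9 of 31 LTR families, 0 of 22 CR1 families (Fisher's exact test of LTR against CR1, two-sided p = 0.0069) and Mariner1_GG. EAVHP_I-int was 94.4% and 100% sense after oxidation and 76.9% and 78.4% in total libraries, and GGLTR10C-int was 100% sense in both oxidized libraries. GGLTR3F1, the most abundant of the 9, was 71.7% and 67.2% sense, with 24058 and 32704 reads. The others were ENS1-int, GGERVK1-int, GGLTR10D-int, GGLTR5B, GGLTR7-int and GGLTR7A, and all 9 rose after oxidation. Chance from few molecules would give different families in the 2 oxidized libraries, yet of 11 LTR families with a sense majority in either, 9 (81.8%) had it in both, at a median of 22.4 molecules in the lower library. That share lies barely above the bound of 80% set for it. Families share reads and are not independent replicates.

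The rise of a family went with its antisense share. Across 26 CR1 families with at least 3 CPM in total libraries, the log2 fold change correlated with the antisense share of their reads in the total libraries (Pearson r = 0.854, Spearman rho = 0.817, permutation p = 1e-05 and 2e-05 from 100000 permutations, the first being the smallest these can give). Adjusted over 4 relations both p were 4e-05, and without the 2 families farthest from the median share r was 0.756. Across 37 LTR families r was 0.429 (permutation p = 0.0057, adjusted 0.0057) and rho 0.510 (permutation p = 0.0016, adjusted 0.0022), and r was 0.370 without the 2 farthest. Unmethylated background on both strands, diluting some CR1 families, stays open. On the reverse strand alone rho was 0.706, above the 0.409 set as the limit for dilution, but that limit was wrong: such background adds reads to the reverse strand as well and would keep rho high, so the test decides nothing. Both measures also use the same total-library counts. Since CR1 reads were 97.7% antisense after oxidation, sense reads in total libraries lower the fold change and the antisense share alike. The relation is thus partly built in, and the permutation p does not allow for that. These are correlations across families, which share reads and are not independent. Beyond this the reason for the relation was not found.

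Other genes appeared in one oxidized library and not in the other. Lower depth is argued against: total libraries thinned to the 10981001 reads of the shallower oxidized library still showed 8029 and 8239 other-gene IDs, not 647. A difference between the 2 samples in the total reads of these genes is argued against as well. Genes of oxidized replicate 1 alone stood 1.11 times higher in total replicate 1 than 2, relative to genes of oxidized replicate 2 alone. The 95% bootstrap interval was 0.844 to 1.36, where 1.5 was needed. A difference confined to RNAs that withstand oxidation need not show in total libraries, where far more other-gene IDs had reads, so it stays open. That few molecules survived oxidation and each was copied many times stays open. IDs with 51 to 200 reads outnumbered those with 3 to 50 by 1.79 and 1.95 times in the oxidized libraries, against 0.0253 and 0.0237 in the total libraries, but these limits were set around a peak already seen, so the ratio restates that peak and tests nothing. The estimate of reads per molecule rests on the same peak, and each count of molecules here holds only as far as that estimate does. That estimate used only IDs with at least 20 reads. The oxidized libraries also held 149 and 96 IDs with 1 to 2 reads, which the ratio leaves out, and 139 and 135 with 3 to 50. A fixed number of reads per molecule does not account for these IDs.

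Features lower after oxidation may partly be features whose few molecules were missed. A first test counted how many of the 579 lower features expected under 3 molecules stayed lower as molecules; it gave 0, which such low counts fix in advance, and it was replaced by the number at 0 molecules against that of an unchanged share. Among miRNA IDs 194 of 209 were at 0 against 113 expected (excess 81.0, SD 6.3), and 20 molecules were seen against 162 expected. If the estimate holds, missed molecules alone would not give so large a gap. Its size is only approximate, because rounding turns few reads into 0 molecules and the SD leaves out uneven capture. Among other-gene IDs 525 of 663 were at 0 against 459 (excess 66.0, Poisson SD 10.7, which leaves out uneven capture), but 665 molecules were seen against 298 expected, so the set as a whole was not depleted and missed molecules stay open there. Among TE families 17 of 54 were at 0 against 27.1 (difference -10.1, SD 3.13), which decides nothing about the 15 of 19 lower families in this range because most others rose. Of the 134 lower features expected at 10 molecules or more, Chompy-2_Croc (187 expected) and Eulor9C (19.5) among them, 97.0% stayed lower as molecules. They had been called lower on the same counts, so most were likely to stay. What argues against missed molecules there is that at least 10 were expected at an unchanged share, and only if the estimate holds. Destruction by periodate stays open, as untested.

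The tRNA rows moved apart, and neither of the technical explanations weighed here accounts for it. Loss of miRNA reads lifts all rows by about 1 factor, so by arithmetic it cannot set them apart. The SD of their log2 fold changes was 2.86, or 6.45 times the median SE of 0.443. Rows near 0 reads after oxidation, such as tRNA-Leu-TTA and tRNA-Thr-ACG, widen that SD. The rise of the class is another question, since its share ratio of 1.14 log2 turned to -0.67 with miRNA left out. Chance from few molecules would leave the pairs of libraries unrelated, yet across 41 rows expected at 3 molecules or more the log2 ratios of the first and second same-numbered pair correlated at r = 0.905 (across rows, which are not independent). One further row of this range, tRNA-Thr-ACY, was left out because it had 181 reads in oxidized replicate 1 and 0 in oxidized replicate 2, which goes against agreement. Over all 50 tested rows r was 0.811. Reads shared between near-identical tRNA genes stay open, as untested. That some tRNA fragments carry a 2′-O-methyl or otherwise protected end may be kept as a hypothesis.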
